A study of Mus musculus with 24 samples.

How the data were processed

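The values started from are a table of normalised counts, 1 column per library and 1 line per gene, deposited by the authors. The values are a signal, namely counts that the authors had normalised with DESeq2 before deposit. In all 24 columns 100.0% of the values were whole multiples of 1 step per column, within a tolerance of 0.001 reads that widened for high counts. So 23 of these columns were taken as whole gene counts divided by 1 size factor per library with no scaling for gene length. For male smoke insert 5 the step of 0.989 was judged too near 1 for such a recovery to be claimed, and that library was left out of the tests that need whole counts. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.38.0, HTSeq and DESeq2 with the builds GRCm38 and mm10, and give no order or settings. The aligner and the strandedness of the libraries are not given in the sources used here. Per the labels, RNA libraries were made with a NEBNext Ultra II kit and read on a NovaSeq instrument.

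The authors also deposited 3 DESeq2 tables, for female air and smoke, male air and smoke, and female and male air. Per the file headers these hold a log2 fold change and its standard error in log2 units, a Wald statistic, which is a score, and a p-value with its adjusted p-value. Gene starts and ends in these tables and in the deposited refGene annotation are positions on mm10, a unit classed as other. The deposited fold changes run from smoke to air and from female to male. Their sign was turned here so that a positive value means higher in smoke or in female cells, and each deposited table used the 12 libraries of its own comparison. Their base mean columns were not used here. The tables serve only as a second count, named as the authors' deposited table wherever they are given.

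Genes with a mean normalised count of at least 10 over the 24 libraries were tested, which kept 13549 of 25239. Values were taken as log2 of the normalised count plus 1. One limma fit with eBayes, a mean-variance trend and 1 term per group served 5 two-sided contrasts, which are smoke against air in each sex, female against male in air and in smoke, and the interaction, the female smoke response minus the male smoke response. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors given after ± are the standard error of a log2 fold change or the standard deviation of a mean, as stated. The groups, the tests, the gene lists, the rule for naming genes and most of the alternatives were set before the data were examined.

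Gene lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists within each contrast. Since a preset correlation makes the calls more liberal, the adjusted p with an estimated correlation is given beside each. The 31 lists are xenobiotic metabolism (aryl hydrocarbon receptor), NRF2 and antioxidant, glutathione transferases, motile cilia, basal cell, club and secretory cell, goblet cell and mucus, tuft cell, neuroendocrine cell, ionocyte, airway ion and water transport, tight junction, adherens junction and desmosome, actin cytoskeleton and motility, epithelial-mesenchymal transition, fibroblast, leukocyte, endothelial cell, inflammatory mediators, interferon response, unfolded protein and integrated stress response, heat shock, p53 and DNA damage, cell cycle, squamous and keratinization, oxidative phosphorylation, cholesterol synthesis, sex steroid receptors and metabolism, ribosomal proteins, Y-linked and X-linked sex markers. Lists with fewer than 5 measured members, endothelial cell and Y-linked, were counted but not tested with camera.

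Genes were named by rule. For the smoke comparison in each sex, for the sexes in air and for the interaction, the rule takes the 8 highest and the 8 lowest fold changes among called genes with a mean of at least 50 in the higher group and, in the pairwise comparisons, no overlap between the 6 libraries of each group. It adds the 2 members of each list with the largest absolute fold change in either sex among those called there, the Y-linked genes and Xist. Predicted gene models were counted and not named, and members of a list could be given as examples with their values.

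Where a group holds no reads of a gene, a fold is given as at least the ratio to 3 reads over the whole group. Where it holds 1 to 3 reads, the ratio of group means is given with its 95% counting interval. The reads carry no molecular identifiers, so intervals and floors of this kind cover counting error only.

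The alternatives were TMM scaling, scaling by the library total, quantile scaling, pseudocounts of 0.5 and 5, no filter and a mean of at least 50, robust eBayes, array quality weights, the insert number as a block, only the groups compared, each library left out in turn, and edgeR and DESeq2 on the recovered whole reads of 23 libraries. Lists were also tested with fry, directional and mixed. Fry asks whether the members change at all, where camera compares them with the other genes. A call lost with fry therefore answers a different question. Alternatives added later left out female air insert 1 with female smoke insert 4, or used inserts 1 to 3 or inserts 4 to 6 alone, or used these sets as a block. The versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

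The fit was tested on simulated data of the same size in which 200 of 13549 genes had been changed. For the female smoke contrast limma recovered 64.0% of genes changed by a log2 of 1 and 93.0% of those changed by a log2 of 2, and 3.68% of its calls were false. For the interaction it recovered 39.0% and 75.0%, with 3.39% false. DESeq2 recovered 72.0% and 96.0% of the smoke changes with 12.0% of its calls false, and edgeR 65.0% and 92.0% with 3.68% false. camera gave an unadjusted p under 0.05 to 0.5% of 200 unchanged lists and 100.0% of 50 changed ones. The simulated genes were drawn independently, so this does not test camera on lists whose genes move together. Among pairs of libraries of the same group, male smoke insert 5 left out, none was a duplicate, since the lowest mean chi-square per gene was 2.86, and pairs across groups were not tested. Physiological measurements named in the series description, such as barrier resistance and ciliary beat frequency, were not analysed here. Results of some genes withheld for evaluation are not reported here, though those genes remain in the tests, the lists and the counts of called genes.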

Results

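RNA was sequenced from 24 cultures of mouse tracheal epithelial cells, primary airway cells that form a layer of ciliated, secretory and basal cells when their upper side faces air. The cells came from wild-type FVB/NJ mice aged 7 to 8 weeks and were differentiated at an air-liquid interface for 10 to 14 days. The cultures, grown on inserts, were then held for 10 days under either humidified air or cigarette smoke, where 1 exposure burned 2 cigarettes over about 8 minutes. There were 4 groups of 6 inserts, namely female air, female smoke, male air and male smoke. Library depth ran from 16038813 to 24485024 reads assigned to genes in the 23 libraries whose whole counts were recovered. Fold changes are given on the log2 scale with their standard error (SE, n = 6 per group), and group means as normalised counts with their standard deviation (SD, n = 6). The labels name no donors, so the inserts may be technical replicates of 1 cell preparation per sex. The p-values therefore measure only the spread between these inserts, and a sex difference includes any other difference between the preparations.

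The sex labels fitted the sex-linked genes in all 24 libraries. Xist, the RNA that silences 1 X chromosome in female cells, averaged 10500 ± 3670 (SD, n = 6) in female air and 3.76 ± 1.88 in male air. The lowest female air library stood at 3665 and the highest male air library at 5.84 (exact permutation test, two-sided, p = 0.00216, the smallest that the 924 arrangements can give). No female library of 12 held a read of Ddx3y, Eif2s3y, Kdm5d or Uty, and 12 of 12 male libraries held reads of each.

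In female air insert 1 and female smoke insert 4, gene levels moved with transcript length. In female air insert 1 genes with transcripts of at most 1812 bases lay at a median of 1.22 (log2) above the group's typical value and genes with transcripts of at least 4325 bases at -0.92. Its Spearman correlation across genes between this deviation and length was -0.670, and 5449 genes differed from the group by over 2-fold, against at most 662 in any other female air insert. In female smoke insert 4 the correlation was -0.427, the shortest and longest transcripts lay at 0.56 and -0.53, and 3475 genes differed by over 2-fold. Genes are not independent replicates, so these correlations describe a library and carry no p. Both libraries were kept in the main test, and the number of genes called in each comparison is also given without them, an alternative chosen after seeing the data. Without them camera lost 7 of its 44 list calls, named below.

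**Figure D1:**
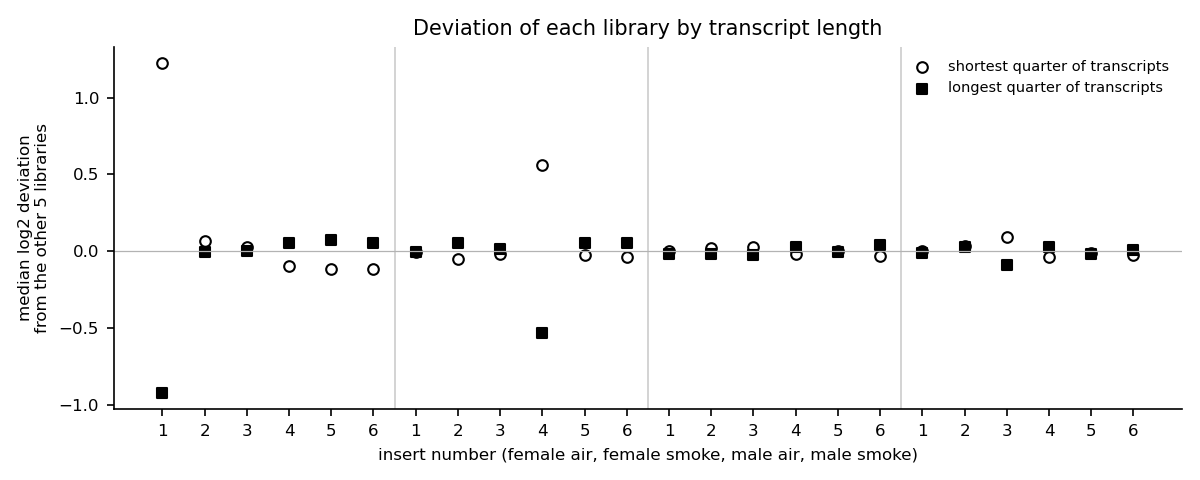
Median log2 deviation of each library from its group (y axis) for the genes with the shortest and the longest transcripts, by insert number (x axis) in the 4 groups. Female air insert 1 reached 1.22 and -0.92 and female smoke insert 4 reached 0.56 and -0.53.

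The smoke comparison in female cells asks how the female epithelium responded to 10 days of smoke. Genes of the cornified envelope, the protein shell of squamous cells, rose most. Sprr2f rose by 7.41 ± 0.45 (SE, n = 6 per group), from a mean of 4.50 ± 2.06 to 1167 ± 1010 (SD), and Sprr2h and Sprr2d, its neighbours on mm10 chromosome 3 between 92339139 and 92387324, rose by 6.34 ± 0.43 and 6.18 ± 0.43. Krt6b, a keratin of stressed and regenerating epithelium (chromosome 15, 101676022 to 101680293), rose by 5.52 ± 0.44, the neutrophil-attracting chemokine Cxcl3 by 4.95 ± 0.47, the prostaglandin synthase Ptgs2 by 5.00 ± 0.51 and the neuronal tubulin Tubb3 by 5.45 ± 0.53. The steepest losses were in C1qtnf3 (-5.59 ± 0.86), Amtn (-5.51 ± 0.80), Sec14l3 (-5.22 ± 1.19), Dcn, which encodes the matrix protein decorin (-4.52 ± 0.80), and Sftpc, a surfactant protein (-4.08 ± 0.79). Nell1 (-4.02 ± 0.63), Cdh26 (-4.02 ± 0.94) and Adamts18 (-3.92 ± 0.74) fell too, and without the 2 libraries with a length trend Sec14l3 stood at -3.51, Sftpc at -2.74 and Cdh26 at -2.63. Some of these sizes rest on female air inserts 4 to 6, where C1qtnf3 stood at 948 to 1047 against 68.5 to 80.6 in inserts 1 to 3, Amtn at 824 to 881 against 54.6 to 176 and Adamts18 at 148 to 226 against 4.56 to 15.5. With inserts 1 to 3 alone C1qtnf3 changed by -3.43 and Amtn by -3.80, and Adamts18 (-1.27, adjusted p = 0.176) and Nell1 (-2.96, 0.0605) did not pass.

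Motile cilia genes fell together in female cells: of 66 measured, 63 fell and none rose, or 65 adjusted over the list alone. The axonemal dynein Dnah9 changed by -3.36 ± 1.09, Tekt4 by -3.19 ± 0.97 and Gmnc, a regulator of multiciliated fate, by -2.48 ± 0.64. For motile cilia camera gave adjusted p = 7.23e-15, and adjusted p = 0.475 with an estimated correlation. The level of the list varied widely among the female smoke inserts, at a mean of -0.74 ± 2.41 (SD, n = 6) with insert 4 at -5.30, against 1.82 ± 0.35 in female air. Without the 2 libraries with a length trend 60 members fell and the median moved from -2.62 to -1.55, and Dnah5 moved from -3.43 to -2.06 without female smoke insert 4 alone. Other cell type markers fell as well. Of 8 ionocyte genes 7 fell (8 adjusted over the list alone), with the proton pump subunits Atp6v1b1 at -3.37 ± 0.45 and Atp6v1c2 at -2.31 ± 0.36. For ionocyte genes camera gave adjusted p = 0.000294, and adjusted p = 0.102 with an estimated correlation. Among 22 club and secretory cell genes 9 fell and Muc20 rose by 1.04, the same counts adjusted over the list alone, with Scgb1a1 at -3.09 ± 0.85 and Scgb3a2 at -3.19 ± 0.66. For club and secretory cell genes camera gave adjusted p = 0.00431, and adjusted p = 0.552 with an estimated correlation, a list call that was lost without female air insert 1 (adjusted p = 0.0928) and without both libraries with a length trend (0.209). Of 6 fibroblast genes Dcn, Postn (-2.63 ± 0.51) and Col6a1 (-2.08 ± 0.54) fell, and 4 did adjusted over the list alone (adjusted p = 0.0284, adjusted p = 0.339 with an estimated correlation, and 0.0587 without female air insert 5, 0.217 with inserts 1 to 3 alone).

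Proliferation, interferon and sterol genes rose in female smoke. Of 34 cell cycle genes 29 rose (33 adjusted over the list alone), among them the replication helicase subunit Mcm5 (1.90 ± 0.28), Cdc6 (1.68 ± 0.35) and Aurkb (1.59 ± 0.37). For cell cycle genes camera gave adjusted p = 1.04e-12, and adjusted p = 0.351 with an estimated correlation. Of 30 interferon response genes 24 rose (26 adjusted over the list alone), with Ifit3 at 3.93 ± 0.62, Oas3 at 3.64 ± 0.58 and Isg15 at 3.18 ± 0.50. For interferon response genes camera gave adjusted p = 5.34e-11, and adjusted p = 0.339 with an estimated correlation. Of 22 cholesterol synthesis genes 18 rose (20 adjusted over the list alone), with Idi1 at 2.14 ± 0.41. For cholesterol synthesis camera gave adjusted p = 2.03e-09, and adjusted p = 0.339 with an estimated correlation. Among 27 squamous and keratinization genes 15 rose and Krt1 fell by 1.27, or 16 and 1 adjusted over the list alone, and Sprr1a reached 4.87 ± 0.53. For squamous and keratinization genes camera gave adjusted p = 1.75e-09, and adjusted p = 0.102 with an estimated correlation. Of 31 inflammatory mediators 18 rose and Cx3cl1 fell by 1.03, or 20 and 2 adjusted over the list alone, with the calprotectin subunit S100a9 at 5.49 ± 0.55 and Csf3 at 3.25 ± 0.49. For inflammatory mediators camera gave adjusted p = 4.42e-07, and adjusted p = 0.339 with an estimated correlation. The median of that list was 1.40, or 1.42 with Il24, which had no reads in female air, at its bound of at least 4.95-fold higher.

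Stress and detoxification genes changed in part. Of 24 genes of the unfolded protein and integrated stress response 10 rose, the same number adjusted over the list alone, with Trib3 at 2.69 ± 0.48 and Chac1 at 2.26 ± 0.46. For this stress response camera gave adjusted p = 0.000595, and adjusted p = 0.351 with an estimated correlation. Of 22 p53 and DNA damage genes 9 rose and Xpc fell by 0.56, the same adjusted over the list alone, with Pmaip1 at 1.59 ± 0.24 and the cell cycle inhibitor Cdkn1a at 1.13 ± 0.15. For p53 and DNA damage camera gave adjusted p = 0.00189, and adjusted p = 0.286 with an estimated correlation. Of 32 NRF2 and antioxidant genes 11 rose and Cbr1 fell by 0.45, the same adjusted over the list alone, with ferritin heavy chain Fth1 at 1.41 ± 0.32 and the quinone reductase Nqo1 at 1.16 ± 0.33. For NRF2 and antioxidant genes camera gave adjusted p = 0.00683, and adjusted p = 0.515 with an estimated correlation, a list call lost with quantile scaling (adjusted p = 0.0898) and with inserts 1 to 3 alone (0.0614). The actin cytoskeleton and motility list, with 8 of 32 up and 2 down, the same adjusted over the list alone, passed camera (adjusted p = 0.0239, adjusted p = 0.66 with an estimated correlation), and lost its call without female air insert 1 (0.0701), 2 (0.0816) or 3 (0.0881), without female smoke insert 4 (0.137), without both libraries with a length trend (0.2), with quantile scaling (0.335), with inserts 4 to 6 alone (0.663) and with directional fry (0.0729). The xenobiotic metabolism list went both ways, with 5 up and 8 down of 20, or 6 and 8 adjusted over the list alone (adjusted p = 0.975). Cyp1a1 and Cyp1b1, which the aryl hydrocarbon receptor induces, rose by 4.65 ± 0.63 and 3.08 ± 0.27. Its repressor Ahrr had 1 read in female air (ratio 76.8, 95% counting interval 13.8 to 3035). Cyp4b1 (-2.08 ± 0.41) and Cyp2b10 (-1.97 ± 0.35) fell.

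The other lists did not pass camera in female cells. Tuft cell genes had 4 of 9 down (adjusted p = 0.0636), glutathione transferases 2 up and 5 down of 22 (0.173) with Gsta1 at 2.07 ± 0.63 and Gstt1 at -1.64 ± 0.32, and epithelial-mesenchymal transition 1 up and 5 down of 20 (0.376), each count being the same adjusted over the list alone. Tight junction genes had 5 up and 4 down of 27 (4 and 4 adjusted over the list alone, adjusted p = 0.618), with Cldn2 at -2.86 ± 0.47 and Cldn8 at -1.33 ± 0.23. Adherens junction and desmosome genes had 4 up and 2 down of 22 (0.245), basal cell genes 2 up and 4 down of 21 (0.618), airway ion and water transport 4 up and 3 down of 19 (0.965) with Slc26a9 at 2.64 ± 0.34, and sex steroid receptors and metabolism 3 down of 12 (0.498) with Srd5a1 at -1.19 ± 0.30, the same adjusted over the list alone. Srd5a1 changed by -1.97 with inserts 4 to 6 alone and by -0.41 with inserts 1 to 3 alone (adjusted p = 0.246). Leukocyte genes had 1 up and 2 down of 6 (0.483) and neuroendocrine cell genes 1 up and 3 down of 5 (4 down adjusted over the list alone, 0.316). X-linked sex markers had 2 up of 10 (0.251), and of 3 endothelial cell genes Vwf fell by 2.32. Oxidative phosphorylation had 2 up of 40, and 0 adjusted over the list alone (0.376), against 22 up and 1 down without the 2 libraries with a length trend. Of 30 ribosomal protein genes 0 were called by limma, 0 at an unadjusted p under 0.05, and 0 by edgeR and by DESeq2 (0.975), against 7 up without those libraries. Goblet cell and mucus had 3 up and 1 down of 12 (0.981) at a median of -0.33 that turned to 0.15 with quantile scaling. Heat shock had 1 up of 14, Hspd1 at 0.77 (0.653), at a median of 0.07 that turned to -0.01 with it. The median of the 3 endothelial cell genes turned from -0.24 to 0.31. The median, the mean and the camera direction differed in sign for tight junction, airway ion and water transport, xenobiotic metabolism, goblet cell and mucus and ribosomal proteins.

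By limma 4713 of 13549 genes changed in female cells, 2097 up and 2616 down, of which 2015 changed at least 2-fold, and 5948 had an unadjusted p under 0.05. The 6 smoke and 6 air libraries did not overlap for 1691 genes (12.5%, against 0.216% by chance). Without the 2 libraries with a length trend 6188 genes were called, 2970 up and 3218 down, and with the female libraries alone 2857, 1332 up and 1525 down. The balance turned with inserts 1 to 3 alone, at 383 up and 273 down, and with quantile scaling, at 2285 up and 2184 down. The authors' deposited table calls 4255, and the 3714 called there and here all have the same sign.

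**Figure D2:**
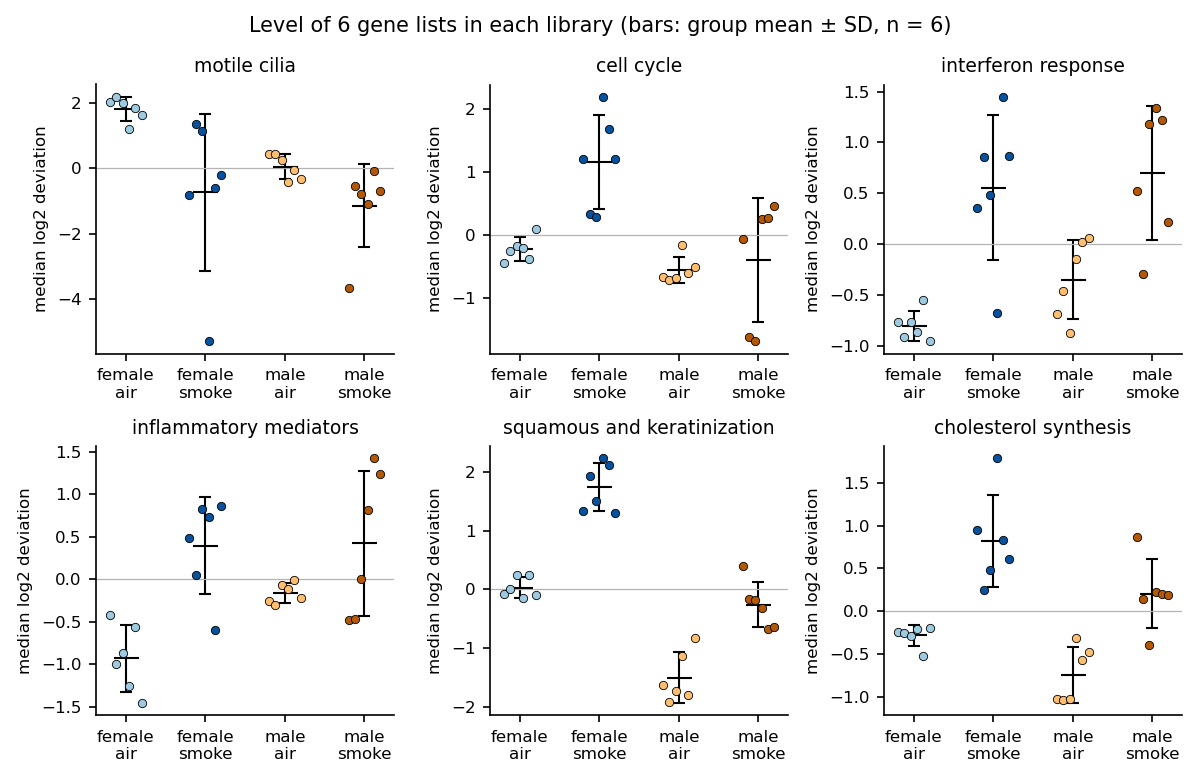
Median log2 deviation of 6 gene lists from the mean of all libraries (y axis) for each library in the 4 groups (x axis), with bars for the group mean ± SD (n = 6). Motile cilia stood at 1.82 ± 0.35 in female air and -0.74 ± 2.41 in female smoke, and squamous and keratinization at 0.03 ± 0.18 and 1.74 ± 0.41.

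The same comparison in male cells asks how the male epithelium responded. The platelet chemokine Ppbp (chromosome 5, 90768517 to 90770062) rose by 7.27 ± 0.43 (SE, n = 6 per group), from 31.95 ± 16.4 to 5857 ± 5170 (SD), Krt6b by 5.32 ± 0.44 and the antimicrobial peptidoglycan binder Pglyrp4 by 5.31 ± 0.41. Cyp1a1 (chromosome 9, 57687927 to 57703824) rose by 4.76 ± 0.63, from 6.79 ± 2.68 to 314.5 ± 307, S100a7a by 4.46 ± 0.64, the cytokine Il24 by 4.44 ± 0.60, Cst6 by 4.33 ± 0.52 and Bcl2l15 by 4.07 ± 0.45. Sprr2d had no reads in male air and was at least 63.2-fold higher in male smoke, and Sprr2h had 1 read there (ratio 153, 95% counting interval 27.5 to 6048). Among the steepest losses were Akr1c14 at -4.32 ± 0.57, Cyp2a5 at -3.49 ± 0.43 (from 4198 to 403.7) and Fmo6 at -3.22 ± 0.41, beside Dcn (-4.37 ± 0.80), Slc6a15 (-3.88 ± 0.68), Gpnmb (-3.33 ± 0.52), Gfra1 (-3.29 ± 0.68) and Fads2b (-3.26 ± 0.28).

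Squamous, sterol, interferon and inflammatory genes rose in male smoke. Of 27 squamous and keratinization genes 15 rose and 2 fell, the same adjusted over the list alone, with Krt6a at 3.42 ± 0.30, Cnfn at 2.97 ± 0.65 and involucrin, Ivl, at 2.92 ± 0.54 against the protease inhibitor Spink5 at -2.07 ± 0.35 and Krt1 at -0.95 ± 0.34. For squamous and keratinization genes camera gave adjusted p = 6.41e-08, and adjusted p = 0.15 with an estimated correlation. Of 22 cholesterol synthesis genes 16 rose (17 adjusted over the list alone), with Hsd17b7 at 1.63 ± 0.34, Idi1 at 1.61 ± 0.41 and Cyp51 at 1.34 ± 0.26. For cholesterol synthesis camera gave adjusted p = 2.63e-08, and adjusted p = 0.53 with an estimated correlation. Of 30 interferon response genes 18 rose (21 adjusted over the list alone), with Oasl1 at 3.35 ± 0.36, Rsad2 at 3.34 ± 0.70 and Isg15 at 2.56 ± 0.50. For interferon response genes camera gave adjusted p = 6.41e-08, and adjusted p = 0.53 with an estimated correlation. Of 31 inflammatory mediators 11 rose and 3 fell, or 15 and 3 adjusted over the list alone, with Il1a at 3.42 ± 0.39, Csf3 at 2.61 ± 0.49 and the alarmin Il33 at 2.09 ± 0.45 up and Cxcl15 (-2.13 ± 0.53), Cx3cl1 (-1.04 ± 0.31) and Icam1 (-0.74 ± 0.25) down. For inflammatory mediators camera gave adjusted p = 0.000118, and adjusted p = 0.53 with an estimated correlation, and the call was lost with inserts 1 to 3 alone (0.346). Within male smoke 15 of the 31 members were lower in inserts 1 to 3 than in inserts 4 to 6, at a median of -1.16. S100a9 had 2 reads in male air (ratio 58.9, 95% counting interval 16.3 to 486). Of 32 actin cytoskeleton and motility genes 10 rose and 1 fell, or 15 and 1 adjusted over the list alone, with tropomyosin Tpm2 at 1.90 ± 0.33 and filamin Flna at 0.97 ± 0.26. For actin cytoskeleton and motility camera gave adjusted p = 0.000102, and adjusted p = 0.53 with an estimated correlation. Of 24 genes of the unfolded protein and integrated stress response 4 rose, the same adjusted over the list alone, among them Manf (0.81 ± 0.20) and the chaperone Hspa5 (0.66 ± 0.16). For this stress response camera gave adjusted p = 0.00059, and adjusted p = 0.53 with an estimated correlation.

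Motile cilia genes lay lower in male smoke as a list, but few members passed the test. Of 66, 5 fell, among them the multiciliogenesis regulators Gmnc (-3.13 ± 0.64), Mcidas (-2.81 ± 0.73) and Myb (-1.34 ± 0.37), and Tubb4b rose by 0.31, against 3 down and 0 up adjusted over the list alone. For motile cilia camera gave adjusted p = 7.07e-05, and adjusted p = 0.704 with an estimated correlation, and the list call was lost with inserts 4 to 6 alone (0.343) and with directional fry (0.189). Without the 2 female libraries with a length trend, which also set the spread used for male cells, 36 members fell. Of 8 ionocyte genes 6 fell, the same adjusted over the list alone. For ionocyte genes camera gave adjusted p = 0.00059, and adjusted p = 0.15 with an estimated correlation. Their member Atp6v1c2 stood at -1.67 ± 0.36. Of 22 club and secretory cell genes 7 fell and 1 rose, or 8 and 2 adjusted over the list alone, with the antimicrobial lectin Reg3g at -2.66 ± 0.49, Scgb3a2 at -2.49 ± 0.66 and Aldh1a1 at -1.64 ± 0.49. For club and secretory cell genes camera gave adjusted p = 0.0332, and adjusted p = 0.69 with an estimated correlation, a list call lost without male smoke insert 1 (0.0734) or 2 (0.06), with inserts 4 to 6 alone (0.313) and with directional fry (0.112). Of 22 glutathione transferases 10 fell and 2 rose, or 10 and 3 adjusted over the list alone, with Gstt1 at -2.16 ± 0.32, Gstm2 at -1.88 ± 0.27 and Gsta1 at 2.39 ± 0.63. For glutathione transferases camera gave adjusted p = 0.0127, and adjusted p = 0.69 with an estimated correlation, a list call lost with directional fry (0.0663). Cell cycle genes rose in 6 of 34 (4 adjusted over the list alone), with Cdc6 at 1.46 ± 0.35. For cell cycle genes camera gave adjusted p = 0.0127, and adjusted p = 0.731 with an estimated correlation, a list call lost without male smoke insert 4 (0.0712), 5 (0.068) or 6 (0.107), with inserts 1 to 3 alone (0.732) and with directional fry (0.35). Heat shock genes rose in 2 of 14 (4 adjusted over the list alone; adjusted p = 0.00974, adjusted p = 0.604 with an estimated correlation), and the list call was lost without male smoke insert 3 (0.0674), with inserts 4 to 6 alone (0.329) and with directional fry (0.0723).

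The other lists did not pass camera in male cells. Xenobiotic metabolism had 4 up and 9 down of 20, or 6 and 9 adjusted over the list alone (adjusted p = 0.223). Ahrr (3.37 ± 0.50), Cyp1b1 (2.00 ± 0.27) and Tiparp (1.80 ± 0.27) rose beside Cyp1a1, and Cyp2b10 (-2.43 ± 0.35) and Cyp4b1 (-2.38 ± 0.41) fell. Airway ion and water transport had 3 up and 9 down of 19, or 3 and 10 adjusted over the list alone (0.0702), with the sodium channel subunits Scnn1b at -2.68 ± 0.34 and Scnn1g at -1.59 ± 0.26 and the potassium channel Kcnn4 at 2.57 ± 0.38. NRF2 and antioxidant had 4 up and 2 down of 32, or 7 and 2 adjusted over the list alone (0.11), against 11 up and 4 down without the 2 libraries with a length trend. The p53 and DNA damage list had 5 up and 2 down of 22 (6 and 3 adjusted over the list alone, 0.083), tuft cell 2 down of 9 (3 adjusted over the list alone, 0.0865) and fibroblast 3 down of 6 (4 adjusted over the list alone, 0.11). Basal cell genes had 3 up and 5 down of 21 (5 and 6 adjusted over the list alone, 0.599) and adherens junction and desmosome 2 up and 3 down of 22 (the same adjusted over the list alone, 0.223). Epithelial-mesenchymal transition had 3 up and 2 down of 20 (0.37) and leukocyte 2 up of 6 (0.429), Itgam at 2.61 ± 0.43 and Cd68 at 1.53 ± 0.24, the same adjusted over the list alone. Sex steroid receptors and metabolism had 1 up and 1 down of 12 (0 adjusted over the list alone, 0.458), X-linked sex markers 2 up of 10 (3 adjusted over the list alone, 0.223), neuroendocrine cell 1 up of 5 (0.847) and oxidative phosphorylation 1 down of 40, Sdha at -0.31 (0.703). Tight junction had 2 up and 3 down of 27, or 5 and 3 adjusted over the list alone (0.703), with Cldn2 at -2.69 ± 0.47 and Cldn8 at -1.93 ± 0.23, at a median of 0.03 that turned to -0.03 with quantile scaling. Goblet cell and mucus had 1 up and 1 down of 12 (0.805) at a median of -0.07 that turned to 0.10. Of 30 ribosomal protein genes 0 were called by limma, 1 at an unadjusted p under 0.05, and 0 by edgeR and by DESeq2 (0.116), against 14 up without the 2 libraries with a length trend. Of 3 endothelial cell genes 0 were called by limma, at an unadjusted p under 0.05, by edgeR or by DESeq2. The median, the mean and the camera direction differed in sign for leukocyte, tight junction and goblet cell and mucus.

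By limma 2979 genes changed in male cells, 1323 up and 1656 down, of which 1020 changed at least 2-fold, and 4714 had an unadjusted p under 0.05. The 6 smoke and 6 air libraries did not overlap for 3414 genes (25.2%, against 0.216% by chance). The count was 4596 without female air insert 1, 6398 without both female libraries with a length trend and 6148 with the male libraries alone. The authors' deposited table, made from male libraries only, calls 6883, of which 2951 were called here, all with the same sign. Inserts 1 to 3 and inserts 4 to 6 of male smoke differed in level, with means of 548 and 80.6 for Cyp1a1, 3812 and 1006 for Nqo1, 4549 and 1183 for Hmox1, 1157 and 148 for Gsta1, 1040 and 7559 for Cxcl1 and 423 and 6091 for Ccl20, a grouping chosen after the values were seen. Nqo1 was also higher in inserts 1 to 3 in male air (1434 against 780, adjusted p = 0.00631) and in female air (2414 against 1677, 0.0158). Gsta1 was higher in inserts 1 to 3 in female air (209 against 46.8, 0.0146), and its means lay the same way in male air and female smoke without passing. Between these sets 795 genes were called in male smoke, 680 in female air, 140 in female smoke and 2 in male air.

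The study asks whether the female epithelium is more affected, which the overlap of the responses and the interaction address. Across the 13549 genes the female and male fold changes had a Pearson correlation of 0.721 and a Spearman correlation of 0.709. Over other splits of the male libraries the size of the Pearson correlation had a median of 0.487 and reached 0.744. Many of these splits hold unequal numbers of smoke libraries on their 2 sides and so keep part of the smoke effect. Their values therefore do not show the correlation expected without smoke. Genes called up in both sexes numbered 860 and down in both 1013, against 205 and 320 for independent lists, while 28 were called in opposite directions, against 512. Of the 5791 genes called in either sex, 3799 (65.6%) had the larger absolute fold change in female cells. Over the same 5791 genes the median absolute fold change was 0.692 in female and 0.541 in male cells. A gene has the same standard error in both smoke comparisons, so a gene called in 1 sex alone tends to change more there. The share and the medians therefore largely follow the counts of called genes and are no separate measure of which sex changed more. Without the 2 libraries with a length trend 8784 genes were called in either sex. Over those genes the share was 51.7% and the medians 0.409 and 0.401. The share was 17.3% with inserts 1 to 3 alone and 91.4% with inserts 4 to 6 alone, each over the genes called there. The order of the counts of called genes, 4713 in female and 2979 in male cells, turned to 2857 and 6148 when each sex was fitted alone.

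**Figure D3:**
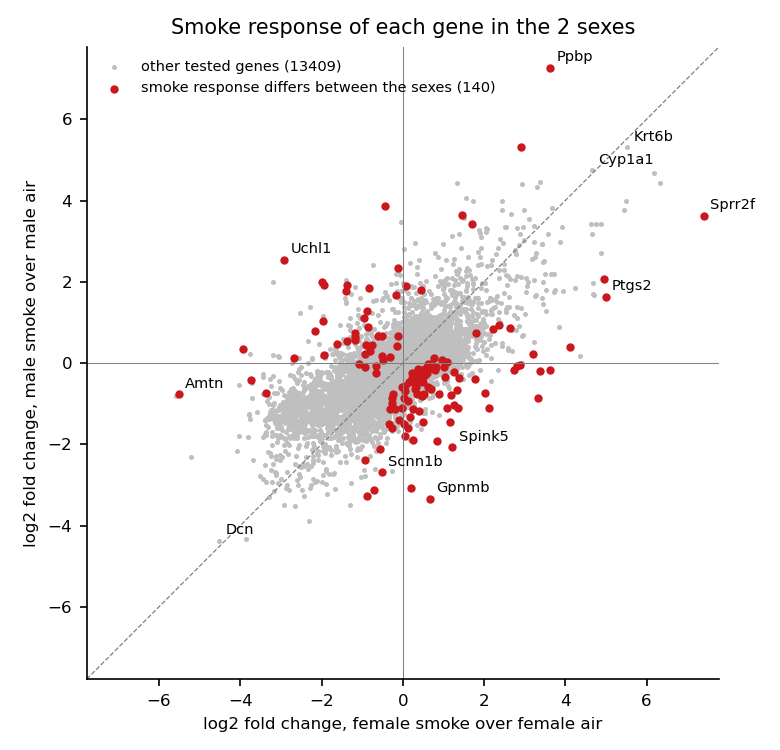
Log2 fold change of each tested gene under smoke in female cells (x axis) and in male cells (y axis), 1 point per gene. The Pearson correlation across the 13549 genes was 0.721, with 860 genes called up in both sexes and 1013 called down in both.

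The interaction names the genes whose smoke response itself differed between the sexes. Spink5, a protease inhibitor of stratified epithelium (chromosome 18, 43963240 to 44022487), rose in female cells from 3423 to 8609 and fell in male cells from 3723 to 1025 (interaction 3.29 ± 0.50, adjusted p = 0.00241). Sprr2f gave 3.78 ± 0.64 (0.0051, but 0.361 with edgeR), Tmprss11a, a transmembrane protease, 4.20 ± 0.83 (0.014), the decoy receptor Il13ra2 3.57 ± 0.69 (0.0114), Ptgs2 3.36 ± 0.73 (0.0246) and Gpnmb 4.01 ± 0.74 (0.00785). Gpnmb had means of 1519 and 2230 in female air and smoke and 261.2 and 29.95 in male air and smoke. On the other side, Ppbp gave -3.64 ± 0.61 (0.00451), with a rise from 1492 to 19460 in female cells from a higher start. Uchl1 gave -5.46 ± 1.10 (0.0147), Myl7 -4.31 ± 0.78 (0.00675), Acta1 -3.97 ± 0.73 (0.00785), Podxl -3.88 ± 0.80 (0.0172) and the lipase inhibitor Angptl4 -3.29 ± 0.62 (0.00978). In male smoke Uchl1 stood at 49.1 to 94.5 in inserts 1 to 3 and at 0.99 to 13.3 in inserts 4 to 6, and Podxl at 79.2 to 527 and at 27.7 to 34.6. With fewer libraries several of these interactions did not pass. With inserts 4 to 6 alone those were Sprr2f (adjusted p = 0.0512), Il13ra2 (0.066), Gpnmb (0.0992), Uchl1 (0.0526), Myl7 (0.124) and Acta1, and with inserts 1 to 3 alone Spink5 (0.0752), Tmprss11a (0.207), Ptgs2 (0.363), Acta1 (0.102), Podxl (0.0591) and Angptl4 (0.33). For Cyp1a1 the interaction was -0.10 ± 0.89 and for Krt6b 0.20 ± 0.63, neither of which passed. Of the 140 genes called, 100 had fold changes of opposite sign, 19 the same sign with the larger change in female cells and 21 with the larger change in male cells, and 26 were called in both sexes in opposite directions.

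Of 34 cell cycle genes 0 passed the interaction by limma, 20 had an unadjusted p under 0.05, 1 passed adjusted over the list alone, and edgeR called 0 and DESeq2 1. Yet camera placed the cell cycle list higher in the female response (adjusted p = 3.9e-11, adjusted p = 0.797 with an estimated correlation). Within male smoke 18 of these genes were lower in inserts 1 to 3 than in inserts 4 to 6, at a median of -1.44, and within female smoke 5 were, at a median of -1.11. The list stood at -1.61 and -1.68 in male smoke inserts 2 and 3, against -0.07 to 0.46 in the other 4, and in female smoke from 0.29 in insert 3 to 2.19 in insert 4. Of 66 motile cilia genes 0 passed by limma, 5 had an unadjusted p under 0.05, 0 passed adjusted over the list alone, and edgeR called 0 and DESeq2 1. Again camera placed the motile cilia list lower in the female response (adjusted p = 6.46e-09, adjusted p = 0.797 with an estimated correlation), with the opposite direction for inserts 1 to 3 alone (0.325). Airway ion and water transport, with Scnn1b (2.16 ± 0.48) and Scnn1g (1.72 ± 0.37) called of 19, the same adjusted over the list alone, and inflammatory mediators, with Ptgs2 and Cxcl3 (2.88) called of 31, or 3 up and 1 down adjusted over the list alone, both lay higher in the female response (adjusted p = 0.0229, adjusted p = 0.797 with an estimated correlation). Interferon response, with Ifit1 (2.89 ± 0.66) called of 30 and 2 adjusted over the list alone (0.0309, adjusted p = 0.856 with an estimated correlation), and p53 and DNA damage, with 0 of 22 called and 1 up adjusted over the list alone (0.0413, adjusted p = 0.797 with an estimated correlation), lay higher, and leukocyte (0.0229), epithelial-mesenchymal transition (0.0248) and heat shock (0.0309) lower, each with adjusted p = 0.797 with an estimated correlation. Of their members limma called 0 of 6, 0 of 20 and 0 of 14, or 0, 4 lower and 0 adjusted over the list alone. With an unadjusted p under 0.05 there were 3, 6 and 1, edgeR called 0, 1 and 0, and DESeq2 0, 2 and 2. Of the 22 p53 and DNA damage genes, where limma called 0, 6 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 1. Directional fry called none of the 9 lists, at adjusted p from 0.269 to 0.67. Leaving out 1 library ended the call of each of these lists but cell cycle and motile cilia. It did so for leukocyte without female smoke insert 2 (0.0506) or 4 (0.0562), and for inflammatory mediators without male smoke insert 1 (0.0598) or 2 (0.0777). The ion transport call ended without female air insert 1 (0.111), female smoke insert 2 (0.0509) or male smoke insert 3 (0.0625), and that of epithelial-mesenchymal transition without female air insert 4 (0.0569), female smoke insert 2 (0.0509) or male smoke insert 5 (0.0535). Heat shock, interferon response and p53 and DNA damage lost theirs in 6, 8 and 12 of the 24 cases, at adjusted p up to 0.194, 0.229 and 0.159. With no filter the camera calls of epithelial-mesenchymal transition (0.0594) and heat shock (0.0576) ended. With a mean of at least 50 those of interferon response (0.0635) and p53 and DNA damage (0.065) ended, the last also with quantile scaling (0.0557). Without both libraries with a length trend the calls of ion transport (0.072), leukocyte (0.0736) and p53 and DNA damage (0.161) ended. With inserts 4 to 6 alone the calls of inflammatory mediators (0.979), ion transport (0.927) and interferon response (0.114) ended and heat shock turned direction (0.486). With inserts 1 to 3 alone those of epithelial-mesenchymal transition (0.338), leukocyte (0.22), interferon response (0.22) and p53 and DNA damage (0.404) ended.

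By limma 140 genes passed the interaction, 94 higher and 46 lower, 96 of them by at least 2-fold, and 1786 had an unadjusted p under 0.05. The balance of directions depended on the alternative, with 253 higher and 253 lower by DESeq2 and 251 higher and 386 lower with inserts 4 to 6 alone. The count was 840 without the 2 libraries with a length trend, 503 higher and 337 lower, 431 without female air insert 1, 246 without female smoke insert 4 and 75 without female smoke insert 6.

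The comparison of the sexes in air asks what differed before any smoke. Beyond Xist (11.11 ± 0.33) and the Y-linked genes, of which Ddx3y was at least 2279-fold, Eif2s3y at least 2419-fold, Kdm5d at least 1643-fold and Uty at least 1136-fold higher in male air, the largest differences by the naming rule were as follows. The envelope transglutaminase Tgm3 (chromosome 2, 130012339 to 130050399) was higher in female air by 9.56 ± 0.45 (SE, n = 6 per group), at 4509 ± 3320 against 4.52 ± 3.31 (SD), Psca by 8.32 ± 0.36, Abca13 by 7.72 ± 0.86, Amtn by 7.35 ± 0.80, Wfdc15b by 7.24 ± 0.48 and the transcription factor Sim2 by 6.98 ± 0.23, at 1465 ± 224 against 11.14 ± 4.13. Tgm7 had 1 read in male air (ratio 1642, 95% counting interval 295 to 64853). Higher in male air were Il13ra2 (-6.41 ± 0.49), Ptgs2 (-5.37 ± 0.51), Pkhd1 (-5.31 ± 0.45) and Elfn1 (-5.06 ± 0.50).

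Motile cilia genes were higher in female air in 30 of 66, or 37 adjusted over the list alone, with Myb at 1.69 ± 0.37 and Mcidas at 1.87 ± 0.73. For motile cilia camera gave adjusted p = 2.64e-06, and adjusted p = 0.942 with an estimated correlation. Without the 2 libraries with a length trend 62 members were higher. Of 27 squamous and keratinization genes 15 were higher and 2 lower, or 18 and 2 adjusted over the list alone, with Krt13 at 5.00 ± 0.30 and Krt6b at 4.80 ± 0.44 against Serpinb2 at -3.18 ± 0.52 and Klk10 at -2.31 ± 0.43. For squamous and keratinization genes camera gave adjusted p = 1.4e-05, and adjusted p = 0.389 with an estimated correlation. Sprr2d was at least 54.6-fold higher. Of 22 p53 and DNA damage genes 13 were lower in female air and Perp, also a desmosome protein, was higher by 1.81 ± 0.17, the same counts adjusted over the list alone, with Eda2r at -2.46 ± 0.28, Fas at -1.85 ± 0.28 and Cdkn1a at -1.36 ± 0.15. For p53 and DNA damage camera gave adjusted p = 1.66e-05, and adjusted p = 0.113 with an estimated correlation. Of 22 adherens junction and desmosome genes 11 were higher and 2 lower, or 12 and 2 adjusted over the list alone, with desmocollin Dsc3 at 2.21 ± 0.20 and Nectin3 at -2.59 ± 0.30. For adherens junction and desmosome genes camera gave adjusted p = 0.00107, and adjusted p = 0.628 with an estimated correlation, and 0.0535 with inserts 1 to 3 alone. Of 19 airway ion and water transport genes 8 were lower and 4 higher, the same adjusted over the list alone, with Scnn1g at -4.79 ± 0.26, the water channel Aqp5 at -4.07 ± 0.36 and Scnn1b at -3.86 ± 0.34 against the anion exchanger Slc26a4 at 4.58 ± 0.73. For airway ion and water transport camera gave adjusted p = 0.0435, and adjusted p = 0.633 with an estimated correlation. That list call was lost without female air insert 1 (0.0992), female smoke insert 3 (0.0504) or 4 (0.0691) or male smoke insert 1 (0.0544), without both libraries with a length trend (0.146), with inserts 4 to 6 alone (0.0681), and with scaling by library total (0.0525) or quantiles (0.0636).

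The other lists did not pass camera between the sexes in air. Inflammatory mediators had 4 higher and 14 lower of 31, or 5 and 16 adjusted over the list alone (adjusted p = 0.124), with Cxcl2 at -3.31 ± 0.87 and Cxcl1 at -3.08 ± 0.60 beside Il1a at 3.67 ± 0.39, and interferon response 2 higher and 9 lower of 30 (0.076), with Ifit1 at -3.98 ± 0.47. Sex steroid receptors and metabolism had 5 higher and 2 lower of 12 (0.115), with the estradiol-oxidising Hsd17b2 at 4.68 ± 0.34 and Srd5a1 at 2.10 ± 0.30, and Greb1, an estrogen-responsive gene, had 2 reads in male air (ratio 176, 95% counting interval 48.7 to 1454). Epithelial-mesenchymal transition had 8 higher and 2 lower of 20 (0.0545), with Tgfbi at 4.19 ± 0.31. Leukocyte had 2 higher of 6 (0.076), Laptm5 at 6.54 ± 0.50 and Itgam at 5.28 ± 0.43, heat shock 5 higher of 14 (0.076), X-linked sex markers 4 higher and 1 lower of 10 (0.115). Goblet cell and mucus had 3 higher and 1 lower of 12 (0.399), club and secretory cell 4 higher and 6 lower of 22 (0.399), actin cytoskeleton and motility 9 higher and 2 lower of 32 (0.282) and ionocyte 1 of 8 each way (0.948). In those lists from interferon response on the counts were the same adjusted over the list alone. Adjusted over the list alone, cholesterol synthesis had 9 higher and 2 lower of 22 (8 and 2 over all genes, 0.115), xenobiotic metabolism 5 and 8 of 20 (5 and 7, 0.147) and unfolded protein and integrated stress response 8 and 8 of 24 (7 and 8, 0.95). In the same order, tight junction had 5 and 7 of 27 (4 and 7, 0.399), fibroblast 3 and 2 of 6 (3 and 1, 0.754), tuft cell 1 and 3 of 9 (0 and 3, 0.124) and cell cycle 0 of 34 (2 and 3, 0.512). Where scaling turned a median, NRF2 and antioxidant had 7 higher and 10 lower of 32 (0.652, median 0.03, and -0.11 scaled by library total) and glutathione transferases 5 and 5 of 22 (0.835, 0.13 and -0.02 by quantiles). Likewise basal cell had 7 and 5 of 21 (0.861, 0.07 and -0.07 by library total), neuroendocrine cell 0 and 1 of 5 (0.798, 0.28 and -0.15 by quantiles), each of these 4 with the same counts adjusted over the list alone, and oxidative phosphorylation 1 and 1 of 40 (0 adjusted over the list alone, 0.861, 0.12 and -0.02 by library total). Of 30 ribosomal protein genes 0 were called by limma, 1 at an unadjusted p under 0.05, 8 by edgeR and 0 by DESeq2 (0.115). Of 3 endothelial cell genes 0 were called by limma, at an unadjusted p under 0.05, by edgeR or by DESeq2, with a median of 0.07 that turned to -0.31 by quantiles. The median and the mean differed in sign for NRF2 and antioxidant, neuroendocrine cell and basal cell.

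By limma 5282 genes differed in air, 2713 higher in female and 2569 higher in male cells, 2237 of them by at least 2-fold, and 6479 had an unadjusted p under 0.05. The groups did not overlap for 4502 genes (33.2%, against 0.216% by chance). Without the 2 libraries with a length trend 7557 genes were called, 3841 higher in female and 3716 higher in male cells. The balance of directions depended on scaling, with 51.4% of called genes higher in female cells in the main test and 38.1% when scaled by library total, which placed the median gene at -0.11, against 0.02 in the main test. The authors' deposited table calls 6926, of which 4994 were called here, all with the same sign.

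Under smoke the sexes differed in some of the same lists. Krt6b stood higher in female smoke by 5.00 ± 0.44 (SE, n = 6 per group), Il1a by 4.89 ± 0.39, Cnfn by 4.46 ± 0.65, Spink5 by 3.13 ± 0.35 and Cyp2a5 by 3.60 ± 0.43. Scgb1a1 stood at -4.67 ± 0.85. Of 27 squamous and keratinization genes 19 were higher and 1 lower, or 19 and 2 adjusted over the list alone. For squamous and keratinization genes camera gave adjusted p = 1.2e-09, and adjusted p = 0.124 with an estimated correlation. Of 34 cell cycle genes 23 were higher, or 25 adjusted over the list alone, with Aurkb at 1.69 ± 0.37. For cell cycle genes camera gave adjusted p = 3.21e-07, and adjusted p = 0.895 with an estimated correlation. Adherens junction and desmosome genes were higher in 13 and lower in 2 of 22, with Dsc3 at 3.26 ± 0.20. For adherens junction and desmosome genes camera gave adjusted p = 0.000298, and adjusted p = 0.563 with an estimated correlation. Genes of p53 and DNA damage were lower in 13 and higher in 1 of 22, with Eda2r at -1.56 ± 0.28, and both lists had the same counts adjusted over the list alone. For p53 and DNA damage camera gave adjusted p = 0.000324, and adjusted p = 0.166 with an estimated correlation. Cholesterol synthesis genes were higher in 10 and lower in 1 of 22, or 12 and 1 adjusted over the list alone. For cholesterol synthesis camera gave adjusted p = 0.0137, and adjusted p = 0.895 with an estimated correlation, a list call lost without female smoke insert 4 (0.137), without both libraries with a length trend (0.111), with inserts 1 to 3 alone (0.6) and with directional fry (0.0634). Motile cilia genes were higher in 6 and lower in 1 of 66, or 1 and 0 adjusted over the list alone (adjusted p = 0.243), and higher in 42 and lower in 1 without the 2 libraries with a length trend. Of 30 interferon response genes 1 was lower and 0 adjusted over the list alone (adjusted p = 0.578).

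By limma 4364 genes differed under smoke, 2297 higher in female and 2067 higher in male cells, 1822 of them by at least 2-fold, and 5606 had an unadjusted p under 0.05. Of these 52.6% were higher in female cells, and 34.8% when scaled by library total, which shifted the median gene by -0.15. The groups did not overlap for 2381 genes (17.6%, against 0.216% by chance), and 6967 genes were called without the 2 libraries with a length trend.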

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

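The test of female air insert 1 for a trend with transcript length within the library, the test of its depth and the test on the genes called between inserts of male smoke were chosen only after the result was seen. For each group of 6 libraries and each named gene, the gap between the most extreme library and its nearest neighbour was divided by the range of the group and compared with Dixon's 95% critical value. Chance passes about 1 in 20 groups, or 18.6 of the 373 tested, and 44 passed. Of these, 20 lay in female air insert 1 and 8 in female smoke insert 4.

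In female air insert 1 the ratio was 0.911 for Abca13, 0.909 for Muc4, 0.833 for Idi1, 0.807 for Ddx3x, 0.789 for Itgam, 0.765 for Rrm2, 0.751 for Dsc2 and 0.720 for Xist, each lying low. The library lay high for Sprr2h (0.851), Bcl2l15 (0.826), Hspd1 (0.815), Hsd17b2 (0.768), Fth1 (0.719), Sftpc (0.719), Wfdc15b (0.706), Myl7 (0.693), Scgb3a2 (0.688), Psca (0.682), Atp5b (0.670) and Dapl1 (0.644). Female smoke insert 4 lay low for Gpnmb (0.803), Dnah5 (0.720), Sec14l3 (0.669) and Cdh26 (0.665), for the level of the motile cilia list (0.674) and for the correlation of deviation with transcript length (0.773). It lay high for Atp5b (0.706), Bcl2l15 (0.653), Sdha (0.644) and Hspd1 (0.636).

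In the male smoke group insert 1 lay high for Bcl2l15 (0.796) and Il24 (0.706) and low for Chga (0.693) and for the motile cilia list (0.715). Insert 2 lay low for Aadat (0.630). Insert 3 lay low for Tmprss11a (0.787) and high for Hspa1b (0.635) and Acta1 (0.626). Insert 4 lay low for Dcn (0.714) and insert 5 high for Tgm3 (0.639). Insert 6 lay low for Hsd17b2 (0.778) and Sprr2h (0.648). In male air insert 2 lay high for Cxcl3 (0.639) and for the share of reads on the ribosomal RNA gene Rn45s (0.850), and insert 4 high for Rrm2 (0.668) and for the cell cycle list (0.642). In the female groups, air insert 5 lay high for Pmaip1 (0.701) and low for the cholesterol synthesis list (0.702), air insert 6 high for Nell1 (0.642), smoke insert 2 high for Ddx3x (0.879), and smoke insert 3 had the most reads (0.682).

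For 22 named genes the interaction test of limma passed (log2, female response minus male response). Of these, Amtn (-4.74), Adamts18 (-4.26) and Aadat (3.27) give no measure of a sex difference in response, since 1 sex had almost no level from which to fall and the value is the fall in the other. Amtn stood at 0 in all male smoke libraries and at most at 2.21 in male air, Adamts18 at most at 2.77 in any male library and Aadat at most at 3.42 in any female library. Lower in the female response were Uchl1 (-5.46), Myl7 (-4.31), Acta1 (-3.97), Podxl (-3.88), Ppbp (-3.64), Angptl4 (-3.29), Atp6v1b1 (-2.63), Pglyrp4 (-2.40) and Psca (-2.18). Higher in it were Scnn1b (2.16), Fads2b (2.39), Cxcl3 (2.88), Aldh1l2 (2.98), Spink5 (3.29), Ptgs2 (3.36), Il13ra2 (3.57), Sprr2f (3.78), Gpnmb (4.01) and Tmprss11a (4.20).

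Female air insert 1 stood apart from its group in 5449 genes over 2-fold, and its deviation fell with transcript length (Spearman correlation across genes -0.670, against -0.427 to 0.329 in the other 23 libraries). A loss of long transcripts in that library, as from degraded RNA, is therefore a candidate explanation for part of the pattern. It did not account for all of it, since 2816 genes stayed over 2-fold once the median deviation at each length was subtracted, against at most 646 in the other female air libraries. Low depth is argued against, since its depth of 16.63 M reads lies within the 16.29 to 20.66 M of the others. The labels set this insert apart in no way, so no biological explanation was tested.

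In female smoke insert 4 the 66 motile cilia genes lay at a median of -5.16 from the other 5 female smoke libraries. A length trend in that library is argued against as the source, since the median was -5.51 once the median deviation at each length was subtracted, with the 75th percentile at -3.36. Whether the insert lost ciliary transcripts jointly, as with fewer ciliated cells, stays open: 54 of 66 genes (81.8%) lay at least 4-fold below the median of the other 5, between the 50% and 90% that had been named as bounds for the test. Smoke itself, which the design names, could act unevenly between inserts, and this was not tested.

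Male smoke inserts 1 to 3 and inserts 4 to 6 differed, with 795 genes called between them. The same sets differed in 680 genes in female air, 140 in female smoke and 2 in male air, so the split is not particular to male smoke. The spread in these tests was pooled over the 4 groups, so the count of 2 may understate the difference within male air. In male air too, libraries of 1 set lay closer to each other than to those of the other set. A batch with the same effect at equal insert numbers was tested as the source of the male smoke difference as a whole. Across 13549 genes the difference had a mean correlation of -0.148 with the same difference in the other 3 groups (-0.067 in female air, -0.255 in female smoke, -0.120 in male air), and 96.1% of 8000 splits gave one as high. Across the 795 called genes alone the mean was -0.053 (-0.106, -0.008 and -0.046 in the same order), and 70.2% of 8000 splits gave one as high. Female air insert 1 and female smoke insert 4 stayed in the test, which was not repeated without them. It therefore cannot decide for the female groups, while the values of male air, -0.120 and -0.046, go against such a batch. Over all groups, differently numbered inserts of the same set correlated across groups at a median of 0.0544 and inserts of different sets at -0.0539. A weak split shared across groups stays open. Nqo1 was higher in inserts 1 to 3 of male smoke, male air and female air at an adjusted p under 0.05. Gsta1, Hmox1 and Slc7a11 had higher means there in all 4 groups, while Txnrd1 had lower means there in both female groups. The NRF2 and antioxidant list had a positive median in each group, at 0.40 in female air, 0.02 in female smoke, 0.13 in male air and 0.53 in male smoke. For these genes a difference shared by insert numbers stays open. A batch whose effect differs between groups stays open too. A length trend is argued against, with a Spearman correlation of -0.067 across genes. Uneven delivery of smoke within the group stays open as a hypothesis, since the labels give no dose per insert, and it was not tested.

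Other splits of the same inserts did not reach the gene counts in any comparison. Of 100 splits drawn from the 462 possible for each pair of groups, only the real one, 1 of 100, gave as many genes, the lowest share such a draw can give. The other splits mix the groups, which adds any difference between the groups to their spread, so their counts are low in part by construction. The inserts may be technical replicates, so chance between cell preparations was not excluded. The real count and the highest of the others were 4713 and 2546 for smoke in female cells, 2979 and 634 for smoke in male cells, 5282 and 2231 for the sexes in air and 4364 and 2011 for the sexes in smoke. For the interaction, with sex labels shuffled within each exposure, they were 140 and 0, again 1 of 100. For the correlation of the smoke responses 3 of 100 splits were as high, with 0.721 for the real split, a median size of 0.487 over the others and 0.744 for the highest other. Even among these inserts chance was not excluded for the number of lists camera called, with 22 splits giving as many for smoke in female cells (13 real, highest other 19), 41 in male cells (12 and 19), 87 for the sexes in air (5 and 14), 98 for the sexes in smoke (5 and 19) and 65 for the interaction (9 and 17). The reason why other splits call as many lists was not tested.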

How the results depend on the processing

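The tests on inserts 1 to 3 or 4 to 6 alone or with these sets as a block, and the omission of female air insert 1 with female smoke insert 4, were chosen only after the result was seen. Male smoke insert 5 was left out of edgeR and DESeq2 after its values were seen, because its step of 0.989 was judged too near 1 to claim whole reads. The other alternatives were planned. Of 166 gene results 166 kept their direction and their side of the threshold with TMM scaling and with robust eBayes, 155 when scaled by library total (9 weaker, 2 stronger), 155 with quantile scaling (5 weaker, 3 stronger, 3 reversed), 154 with edgeR (8 weaker, 4 stronger) and 156 with DESeq2 (4 weaker, 6 stronger). With fewer libraries, inserts 1 to 3 alone kept 115 (45 weaker, 3 stronger, 3 reversed) and inserts 4 to 6 alone 134 (25 weaker, 1 stronger, 6 reversed), and array quality weights kept 149 (1 weaker, 15 stronger, 1 reversed). With 1 library left out 3784 of 3984 cases kept both, 164 were weaker, 29 stronger and 7 reversed. Among 44 list results 44 kept both with TMM scaling, 43 by library total, 40 with quantile scaling, 37 without the 2 libraries with a length trend, 33 with inserts 1 to 3 alone, 35 with inserts 4 to 6 alone, 28 with directional fry and 0 with an estimated correlation, and 1003 of 1056 did with 1 library left out. The lowest library held 16038813 reads, a depth at which folds against groups with 0 to 3 reads can be given only as bounds or ratios with an interval.

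The counts of called genes, in the order smoke in female cells, smoke in male cells, sexes in air, sexes in smoke and interaction, were 4713, 2979, 5282, 4364 and 140. Requiring at least 2-fold left 2015, 1020, 2237 and 1822 in the pairwise comparisons, by construction. Array quality weights gave 7709, 6677, 9490, 6601 and 2420. Without the 2 female libraries with a length trend smoke in male cells gave 6398, the sexes in smoke 6967 and the interaction 840. Only the groups compared gave 2857 for smoke in female cells and 6148 in male cells. Inserts 1 to 3 alone gave 656 for smoke in female cells, 2859 for the sexes in air and 40 for the interaction, and inserts 4 to 6 alone 931 for smoke in male cells and 637 for the interaction, with fewer libraries. For the interaction quantile scaling gave 212 and DESeq2 506. The cause was not tested except where fewer libraries or the fold limit shows it.

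With an estimated correlation camera called 0 lists in each of the 5 contrasts, against 13, 12, 5, 5 and 9 with the preset one. Mixed fry, which asks whether members change in either direction, called 20 for smoke in female cells, 24 for the sexes in air, 21 for the sexes in smoke and 4 for the interaction. Directional fry called 12 for the sexes in air, 9 for the sexes in smoke and 0 for the interaction. For the sexes in air no filter gave 8, inserts 4 to 6 alone 10 and only the groups compared 8. Inserts 4 to 6 alone gave 15 for the sexes in smoke and 14 for the interaction. The correlation of the smoke responses was 0.596 with inserts 1 to 3 alone and 0.575 with inserts 4 to 6 alone. The cause was not tested.

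With 1 library left out the counts ran from 4149 to 6243 for smoke in female cells, from 2110 to 4596 in male cells (4596 without female air insert 1), from 4685 to 6067 for the sexes in air, from 3901 to 5919 for the sexes in smoke and from 75 to 431 for the interaction. The interaction gave 431 without female air insert 1 and 246 without female smoke insert 4. It gave 81 and 84 without female air inserts 4 and 6, 85 and 75 without female smoke inserts 5 and 6, and 90 without male smoke insert 2. Without male air inserts 1, 2, 3, 5 and 6 it gave 76, 83, 77, 84 and 83. Lists called ran from 12 to 15 for smoke in female cells, 11 to 13 in male cells, 4 to 7 for the sexes in air, 5 to 9 for the sexes in smoke (9 without female smoke insert 3, 8 without male smoke insert 3) and 3 to 11 for the interaction (3 without female smoke insert 2). The correlation ran from 0.688 to 0.740.

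Among the gene values that reversed, Hsd17b2 in male cells was called in the main test and the others were not. In female cells Scnn1b turned to 0.46 with inserts 4 to 6 alone, Tpm2 to -0.010 with inserts 1 to 3 alone and from -0.036 without female smoke insert 4 to 0.52 over the libraries left out, and Hspa1b to -0.014 with quantile scaling, -0.034 with inserts 1 to 3 alone and -0.014 without female air insert 5, with 0.10 the highest. Xist turned to -0.016 with quantile scaling, -0.46 with inserts 4 to 6 alone, -0.20 without female air insert 1 and -0.060 without female smoke insert 1, with 0.29 the highest. In male cells inserts 4 to 6 alone gave Lyz2 0.18, Atp5b -0.0032, Hsd17b2 -0.035 and Ddx3x -0.089, and Ddx3x turned to -0.074 with quantile scaling and -0.037 with array weights. Srd5a1 turned to -0.021 with inserts 1 to 3 alone, -0.0095 without male air insert 5, -0.044 without male smoke insert 1 and -0.0013 without male smoke insert 6, with 0.089 the highest. For the interaction the motile cilia list turned with inserts 1 to 3 alone (adjusted p = 0.325) and heat shock with inserts 4 to 6 alone (adjusted p = 0.486). The cause was not tested.

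The labels do not say that an insert number pairs libraries. Over 36 pairs of groups and numbers the deviations of same-numbered inserts correlated at a median of 0.0692 (lowest -0.242, highest 0.367), 15 over 0.1, and 5 libraries correlated best with their own number. Across groups, differently numbered inserts of the same set, as named above, correlated at a median of 0.0544. Inserts of different sets correlated at -0.0539. The median for equal numbers therefore lay near that for the same set, and shows little pairing beyond the sets. The main test had no term for these sets. With the insert number as a block the counts were 4534, 2798, 5202, 4235 and 112, in the same order as above.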

Other observations

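The test of X-linked genes and the gene families below were chosen only after the result was seen. Beyond the lists, members of some gene families were counted, and no family was tested as a group. Of all tested genes 34.78% were called under smoke in female cells and 21.99% in male cells, against which the counts can be read. All 8 measured Sprr genes rose in female cells and 7 of 8 in male cells, at medians of 4.81 and 3.06. Of 28 keratin genes 13 rose and 2 fell in female cells and 13 rose and 1 fell in male cells, with Krt5, Krt6a, Krt6b, Krt7, Krt16, Krt76, Krt80, Krt87 and Krt90 rising in both. Of 13 S100a genes 7 rose and S100a1 fell in each sex. Of 6 kallikreins 4 rose in female and 5 in male cells, and of 6 Tmprss11 proteases 4 rose in each. Among 17 genes whose symbols begin with Cyp2, a prefix that also takes in Cyp21, Cyp26 and Cyp27 genes, 9 fell and 1 rose in female cells and 12 fell in male cells, and of 19 aldehyde dehydrogenases 7 fell and 2 rose in female and 11 fell in male cells. Other families went both ways, such as 13 Serpinb genes, of which 4 rose and 3 fell in female cells and 2 rose and 1 fell in male cells.

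Some families differed in number between the sexes, which was not tested for the families as such. The numbers in male cells depend on the fit, since 2979 genes were called there in the main test and 6398 without the 2 female libraries with a length trend. Of 26 collagen genes 11 fell and 2 rose in female cells and 3 fell and 2 rose in male cells. Of 35 kinesins 11 rose in female cells, among them the mitotic Kif11, Kif20a and Kif23, and 7 fell, among them Kif9, Kif27 and Kif3a, known from cilia. In male cells 1 kinesin rose and 1 fell. Of 8 Cxcl chemokines 6 rose in female cells, 3 rose and 1 fell in male cells, and 7 were lower in female air than in male air. The 4 measured Il1 family genes, Il1a, Il1f6, Il1f9 and Il1rn, were all higher in female air, and 3 rose under smoke in female and 4 in male cells.

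The sex difference in air was not concentrated on the X chromosome. Of 416 X-linked genes 164 were called, against 5114 of 13128 autosomal genes. The odds ratio was 1.02 with a 95% interval of 0.835 to 1.25 (Fisher's exact test, two-sided, p = 0.878), so a higher share of X-linked genes among the differences is argued against beyond that bound.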
